A study of Cymbidium longibracteatum with 2 samples.

How the data were processed

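Leaf RNA was extracted with Trizol and made into 2 libraries, 1 of the green parent and 1 of the yellow variant, by Illumina protocols, per the labels' protocols. The plants had grown for 1 year at 25 °C by day and 20 °C by night. The submitters' processing notes name CASAVA 1.7. The assembler, the transcript set, the aligner, the counting tool, any filter and the lengths of the unigenes are not given in the sources used here. The authors deposited a single table with an FPKM value per unigene and library, that is, fragments scaled to transcript length and to the mapped fragments of the library, per the file headers, rounded to 3 decimals. FPKM values are already scaled to the depth of each library and the length of each transcript, so they hold no read numbers, and no count model was used. The deposited columns were assigned to the green parent and the yellow variant by their names, which match the sample titles. No reference genome or table of gene names was used, and identifiers are given as deposited. All 61101 identifiers lack a name. The form of the identifiers gives a component number followed by a unigene number within it, and unigenes with the same component number were treated as one component where that is stated.

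With 1 library per group no unigene could be tested for a difference between the groups, and none was. Shuffles of unigenes among components, 100 in number, served only to describe pairs of unigenes within these libraries. The number of plants behind each library is not stated, and each difference is one between these libraries. Before the data were examined, the following were fixed. Log2 ratios were computed as yellow over green on FPKM + 1, among unigenes of FPKM 1 or more in either library. The limit for counting a unigene as different was 2-fold on that scale, which understates the change of unigenes of low level. The rule for unigenes to name in a table without gene names was the 2 with the largest rise and the 2 with the largest fall among those of FPKM 10 or more in either library. Gene lists, 18 in all, were also fixed: chlorophyll synthesis, chlorophyll breakdown, carotenoid synthesis, light-harvesting proteins, the photosystems (2 lists), thylakoid electron transport, carbon fixation, chloroplast biogenesis, plastid gene expression, flavonoid synthesis, stress, senescence, other leaf cell types (3 lists), other organisms and reference genes. None could be evaluated, because the table names no gene.

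Alternatives fixed at the same time were other pseudocounts, other minimum FPKM values, higher fold limits, rescaling to equal sums (TPM), scaling on the median or on the trimmed mean of the log2 ratios (30% trimmed at each end, among unigenes of FPKM 1 or more in both libraries), upper-quartile scaling, and leaving out the 20 most abundant unigenes of each library. The higher fold limits among these were 4-fold and 8-fold. The limits of 16-fold and more, and the limit of FPKM 50, were not among the alternatives fixed beforehand. Restriction to the first part of the table and sums over components were added after the values were seen. So were leaving out the most abundant unigene of the yellow library, and the counts per range of mean FPKM under other scalings. Wherever unigenes were left out, the remaining values of both libraries were rescaled to the same sum. The relative depth was read from the ratios of low values, since unigenes with the same number of reads in both libraries have nearly the same ratio. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

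The calculations were tested on simulated data. Values for the 61101 unigenes were drawn with a planted log2 shift of 0.2, and 120 unigenes were made 32-fold higher and 80 were made 32-fold lower. The trimmed mean recovered a shift of 0.195, and 100% of the planted rises and 100% of the planted falls passed the 16-fold limit. All planted unigenes had a mean FPKM of 10 or more, and the only noise was that of read counting at an assumed depth. Recovery was therefore nearly certain by design. The simulation checks the calculation and does not bear on unigenes of low level.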

Results

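Leaf transcripts were measured by RNA-seq in 2 libraries of Cymbidium longibracteatum, an orchid grown in China as an ornamental. The first library came from the green-leaved parent cultivar 'Longchangsu'. The second came from a yellow-leaved variant that was raised from the parent through tissue culture and has leaves with a coloured margin line. Each library was made from the 5 youngest leaves of each plant mixed together. How many plants entered a library is not stated. With 1 library per group, no value has a replicate error and no difference was tested. The comparison of yellow with green bears on which transcripts differ between leaves of different colour, the question that the series title ties to chloroplast formation. The table gives an FPKM value per library for 61101 assembled transcripts (unigenes). It pairs no identifier with a gene name, so no pigment, photosystem or plastid gene is identified in what follows.

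The libraries were similar in breadth. In the green library 48914 unigenes had a value above 0 and 37954 reached FPKM 1; in the yellow library these numbers were 49931 and 39360. Both libraries reached FPKM 1 for 29133 unigenes, or 47.7% of the table. The green library alone reached it for 8821 (14.4%) and the yellow library alone for 10227 (16.7%), and 5438 unigenes (8.9%) were listed at 0 in both. The deposited values summed to 947801 in green and 1069855 in yellow. Total read numbers are unknown, so no counting interval could be given for any value. The steps between low values gave the relative depth, taking the lowest values to be whole numbers of reads. Of 13666 unigenes below FPKM 2 and above 0 in both libraries, 2994 (21.9%) had a log2 ratio of yellow to green between 0.02 and 0.14, against 281 and 169 in the windows of the same width below and above. Their median ratio, 1.06, is the value of a read in yellow relative to a read in green, which puts the yellow library at slightly lower depth.

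The yellow library held more unigenes at raised than at lowered level, and the imbalance grew with the size of the difference. Of 48181 unigenes that reached FPKM 1 in either library, 9654 (20.0%) were at least 2-fold higher in yellow and 7208 (15.0%) at least 2-fold lower, on the scale of FPKM + 1. At a limit of 16-fold, 217 unigenes were higher in yellow and 30 were lower. At 64-fold, 36 were higher and 2 were lower. On the FPKM + 1 scale only unigenes of higher level can reach these limits, so part of the growth comes with a change of level. Among unigenes of FPKM 10 or more in either library, the ratio of higher to lower rose from 2.21 at 2-fold to 7.23 at 16-fold. Of all 48181 unigenes, 31319 (65.0%) lay within 2-fold. The median log2 ratio was 0.05, with quartiles of -0.52 and 0.73. Across these unigenes, which are not independent replicates, log2(FPKM + 1) in the libraries correlated with Pearson's r = 0.82 and Spearman's rho = 0.63.

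The 2-fold counts rest mainly on unigenes of low level. Among those that reached FPKM 10 in either library, 1990 of 14337 (13.9%) were at least 2-fold higher in yellow and 902 (6.3%) at least 2-fold lower. Rescaling each library to the same sum lowered yellow relative to green by 0.17 on the log2 scale, and the counts at FPKM 1 became 8713 higher and 8155 lower. The counts at 16-fold became 190 higher and 36 lower under that rescaling. Part of its effect comes from 1 unigene, the most abundant of the yellow library. With that unigene left out before rescaling to the same sum, the 2-fold counts at FPKM 1 were 9247 higher and 7619 lower.

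**Figure D1:**
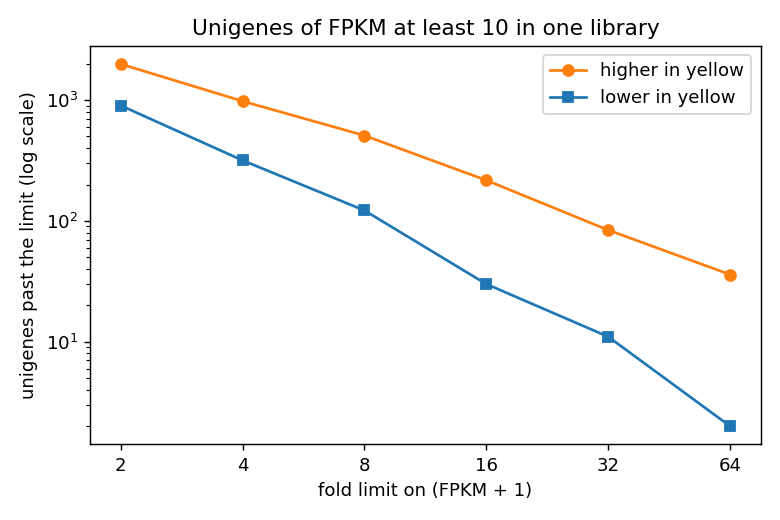
Number of unigenes past each fold limit (x axis, fold on FPKM + 1; y axis, unigenes, log scale) among those that reached FPKM 10 in either library, with circles for unigenes higher in yellow and squares for unigenes lower in yellow. The curves part as the limit rises, from 1990 against 902 at 2-fold to 36 against 2 at 64-fold.

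The 2 unigenes with the largest excess in yellow were close to undetected in green. Unigene c30594_g1 had an FPKM of 692 in yellow and 0.12 in green, a log2 ratio of 9.27 on the FPKM + 1 scale, and ranked 126 by abundance in the yellow library. Unigene c40435_g1 had an FPKM of 296 in yellow and 0.231 in green, a log2 ratio of 7.91. At such low green values the log2 ratio depends on the added constant: with 0.1 in place of 1 it was 11.62 for c30594_g1 and 9.80 for c40435_g1. The 2 unigenes with the largest deficit in yellow remained detectable there. Unigene c21291_g1 had an FPKM of 409 in green and 3.82 in yellow, a log2 ratio of -6.41. Unigene c31936_g2 had an FPKM of 472 in green and 6.10 in yellow, a log2 ratio of -6.06. It shares its component number with 2 other unigenes, and the summed FPKM of that component was 541 in green and 10.5 in yellow, a log2 ratio of -5.56. Unigene c30594_g1 shares its component number with 1 other unigene, which was listed at 0 in green and had an FPKM of 45.7 in yellow.

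**Figure D2:**
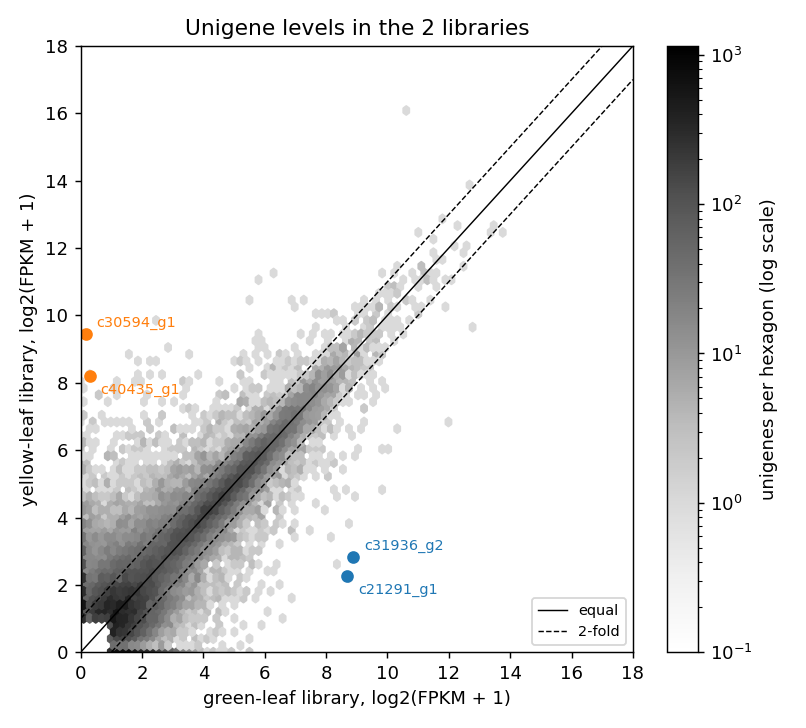
Level of each of the 48181 unigenes that reached FPKM 1 in either library, as log2(FPKM + 1) in green (x axis) and yellow (y axis), with shading for the number of unigenes per hexagon on a log scale, a solid line at equality and dashed lines at 2-fold. The 4 named unigenes are marked, with c30594_g1 and c40435_g1 near 0 in green and c21291_g1 and c31936_g2 well below the lower dashed line.

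Detection in a single library showed the same imbalance among unigenes of moderate level, which are already part of the 2-fold counts above. The values were used as deposited. The yellow library reached FPKM 1 for 4955 unigenes listed at 0 in green, and the green library for 4315 listed at 0 in yellow. The yellow library reached FPKM 10 for 121 unigenes that were listed at 0 in green, and the green library reached it for 32 that were listed at 0 in yellow. At FPKM 50 these numbers were 11 and 0. With a value below 1 in the other library in place of 0, 345 unigenes reached FPKM 10 in yellow and 63 in green.

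A single unigene stood far above all others in the yellow library. Its FPKM was 69423 in yellow, 6.49% of that library's summed FPKM, and 1639 in green, where it ranked 45, which is a 42.4-fold higher value in yellow. The next unigene in yellow had an FPKM of 14259. The most abundant unigene of the green library had an FPKM of 13848, or 1.46% of its sum, and an FPKM of 5350 in yellow, 2.59-fold lower. Both were singled out after their values were seen. Of the 100 most abundant unigenes of each library, 72 were common to both. The 100 most abundant took 23.9% of the summed FPKM in green and 26.7% in yellow.

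The share of unigenes past the 2-fold limit depended on their level. At a mean FPKM from 1 to 2 it was 36.6% of 13747 unigenes, and from 2 to 5 it was 38.0% of 9885. It was lowest, 13.5% of 4492 unigenes, from 30 to 100, and reached 20.3% of 79 unigenes at 1000 or more. Unigenes higher in yellow outnumbered those lower in yellow in each of the 8 ranges with the values as deposited, but in 7 after trimmed-mean scaling, 4 after TPM rescaling and 2 after upper-quartile scaling. The ranges from 5 to 10 and from 10 to 30 kept more higher than lower unigenes under all of these scalings, with 735 against 477 and 663 against 452 after TPM rescaling. At 1000 or more, 10 against 6 became 4 against 14 after TPM rescaling. The interquartile range of the log2 ratio was 1.43 from 2 to 5, 0.62 from 30 to 100 and 1.17 at 1000 or more. With no second library of either group, the spread between like samples at these levels is unknown.

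**Figure D3:**
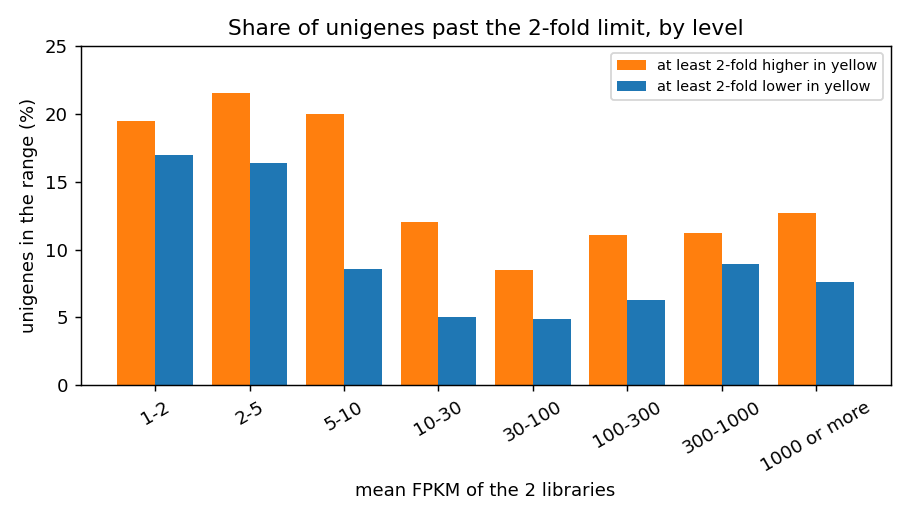
Percentage of unigenes at least 2-fold higher (orange) or lower (blue) in yellow, on the FPKM + 1 scale, by range of the mean FPKM of the libraries. From 1 to 2 the bars reach 19.5% and 17.0%, and from 30 to 100 they reach 8.5% and 4.9%, with the values as deposited; in 4 of the 8 ranges the excess of higher unigenes is lost after TPM rescaling.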

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

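Changed 1 at a time, each of the 17 alternatives, 3 chosen after seeing the data, kept more calls higher than lower. The higher share ran from 50.8% with upper-quartile scaling to 78.2% at 8-fold, against 57.3% as reported. Most kept the deposited scaling. Of the 8 ranges of mean FPKM, only 2 kept that direction with upper-quartile scaling (2190 higher and 2568 lower from 1 to 2). The number of calls varied too, and the causes were not tested unless given here. The settings listed next can, by construction, only lower the counts. Unigenes higher and lower in yellow numbered 2291 and 1048 with a pseudocount of 5. At a minimum FPKM of 5 they numbered 3345 and 1746, and at 10, 1990 and 902. They numbered 2633 and 1543 at a limit of 4-fold, and 668 and 186 at 8-fold. In the first 25160 rows of the table alone, chosen after seeing the data, they numbered 3711 and 1450. Dropping the minimum FPKM changed nothing, because no unigene below FPKM 1 in both libraries can pass 2-fold on FPKM + 1. At FPKM 5 the detected unigenes numbered 16504 in green, 17883 in yellow, 14683 in both, 1821 in green alone and 3200 in yellow alone. With any value above 0, 5732 were in green alone and 6749 in yellow alone. The median log2 ratio moved to -0.0796 with TPM rescaling. It was -0.0401 without the 20 most abundant unigenes of each library. Its sign is therefore set by the scaling. The interquartile range was 0.60 with a pseudocount of 5, Pearson's r was 0.61 with a pseudocount of 0.1, and Spearman's rho was 0.80 at a minimum FPKM of 5. The 4 named unigenes kept their direction in all 24 values, of which 6 moved by more than 1.5-fold, each with another pseudocount. They were picked for the most extreme log2 ratios, and the largest scaling shift was 0.20, so no setting could reverse them. The minimum FPKM of 5 leaves their values unchanged by construction. The alternatives planned for gene lists were not run, since no list could be evaluated. No replicate could be left out and no pairs formed, as each group has 1 library. Unknown read numbers limit every statement on unigenes of low FPKM.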

Other observations

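The tests of library scaling and of ratios at low FPKM below were chosen after the values they use had been seen. The tests of component sums and of opposite pairs were set down before their results were computed but after a first look at the table. The ratio among unigenes without a partner in their component was not set down beforehand. The 16-fold limit used below was not among the fold limits fixed before the data were examined. Unigenes with the same component number tended to differ between the leaves in the same direction. Among 3620 unigenes of FPKM 10 or more in either library that share a component number with another such unigene, there were 2871 pairs within 1533 components. In 252 pairs (8.78%) both members were at least 2-fold away in the same direction, against a median of 63 and a highest value of 91 in 100 shuffles of the unigenes. The log2 ratios within pairs correlated with r = 0.46, against at most 0.043 in the shuffles, a correlation across unigenes that are not independent. In 39 pairs (1.36%) the members were past the limit in opposite directions, against a median of 60 and a range of 47 to 82 in the shuffles. Whether some opposite pairs come from reads divided among near-identical unigenes stays open: the shuffles remove the correlation within components, which by itself lowers the number of opposite pairs, so the bound set beforehand on that number was wrong and the test does not decide. Whether the members are parts of 1 transcript, alleles or gene copies also stays open without sequences.

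The excess of strong differences in the direction of yellow, 217 unigenes higher and 30 lower at 16-fold, a ratio of 7.23, is a pattern that a biologist might follow up first. Library scaling is argued against as the whole cause: the yellow library would have to be lowered relative to green by 0.89 on the log2 scale to bring the ratio under 1.5, while the scalings tried lowered it relative to green by at most 0.20, and TPM rescaling, a relative shift of 0.17, left a ratio of 5.28. Reads divided within components are argued against by a ratio of 7.64 with components summed (191 higher and 25 lower) and by a ratio of 7.29 among the strongly different unigenes without a partner in their component (153 higher and 21 lower); copies in different components were not examined. A difference between the variant and its parent, a difference between individual plants, and RNA of another organism in the yellow leaves all stay open. So does any technical difference between the libraries beyond those examined above, which 1 library per group cannot tell apart from leaf colour. The table has no names or sequences, and the number of plants behind each library is not stated.

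Some of the 2-fold differences at low FPKM may be ratios of small whole numbers of reads. Of the 11771 unigenes past the limit with a highest FPKM below 5, 8474 (72.0%) were listed at 0 in a library. Among the other 3297, windows of log2 ratio placed where 3, 4 or 5 reads to 1 would fall, in either direction, held 1144 unigenes, 3.29 times the mean of the windows beside them. Among unigenes past the limit with a highest FPKM of 10 or more, the same windows held 0.89 times the mean of those beside them. Real differences among the unigenes of low FPKM are not excluded.

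The row order of the deposited table carries information of its own. In the first 25160 rows (41.2%), the distance of the log2 ratio from 0.09 fell with the row number. Spearman's rho was -0.96 across 14464 unigenes of FPKM 5 or more in both libraries. In the other 35941 rows rho was -0.004 across 18429 unigenes above 0 in both libraries. The filters differ and the later rows are of lower level, so the rho values do not compare like unigenes. The highest FPKM had a median of 12.8 in the first part and 1.38 in the rest. Of the later rows, 48.7% were listed at 0 in a library, against 1.6% of the earlier ones. The boundary was itself placed, between rows 20000 and 30000, where the share of rows at 0 in a library changed most sharply. The contrast in that share is therefore partly fixed in advance. Of the unigenes past 2-fold, the later rows held 61.6% of those higher in yellow and 79.9% of those lower in yellow. The last 2000 rows of the first part centred on a log2 ratio of 0.09 (5th to 95th percentile -0.02 to 0.19 over 1275 unigenes). This centre is the value from which the distance above was taken, and it lies above the 0 of equal FPKM. The low unigenes in the window of equal reads also had a median of 0.09. The limits of that window, 0.02 and 0.14, hold its median in a narrow range, so the closeness is partly fixed in advance.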
